A study of Mus musculus with 30 samples.

How the data were processed

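The data came from mice carrying the G158R substitution in Aiolos, the zinc finger transcription factor encoded by Ikzf3, on no copy (WT), 1 copy (het) or both copies (homo). RNA was measured by sequencing in sorted bone marrow cells of the pre-pro B and the later pre-B stage, 3 libraries per genotype and stage, 18 in all. Per the labels' protocols, pre-pro B cells were those positive for B220, AA4.1 and CD43 and negative for IgM and CD24, and pre-B cells those positive for B220, AA4.1 and CD24 and negative for IgM and CD43, and libraries were made with the NEBNext Ultra kit after poly(A) selection. Chromatin immunoprecipitation with sequencing (ChIP-seq) was done in WT and homo cells with antibodies against Ikaros, the related factor encoded by Ikzf1, and against Aiolos. Per the labels, those cells were thymocytes and pre-B cells grown from B220+ IgM− bone marrow on Tst-4 stromal cells with IL-7, SCF and Flt3L. There was 1 ChIP library per antibody, genotype and cell type, and the input samples came without a file of values.

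The deposited RNA table held raw read counts per gene symbol, for 24459 genes and 5 further entries that name no gene. Those entries were kept out of library sizes and tests. Reads in no gene made up 29.85% to 40.15% of a library's total in the table, and reads in more than one gene 0.73% to 0.8824%. The submitters' processing notes name STAR 2.7.0, HISAT2 2.1.0 and MACS2 2.1.1 and the mm10 build without giving each a role. Which program aligned and which counted the RNA reads is not given in the sources used here. Counts assigned to genes ran from 1888871 to 9048055 per library. Some abundant genes had about the same count in libraries of very different depth: Actb had between 2335 and 2650 counts in the pre-pro B libraries. Fold changes of abundant genes between libraries of different depth are therefore less certain than their counting error.

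The deposited peak lists give, for each region, a score, a fold, a −log10 p-value and a −log10 q-value. The score is 10 times the −log10 q-value without its decimals, as checked on the deposited values. Per the labels, the authors called the regions as broad peaks, and the fold is the authors' own ratio of signal to the caller's background. The deposited −log10 p-values and −log10 q-values were used as given. Which control and which thresholds were used for a list is not given in the sources used here. Coordinates are those of the deposited lists, on mm10, counted from 1. No genome sequence was at hand, so the binding motif planned for the peaks was not analysed here. Gene positions came from a RefSeq table of the same assembly without strands, so either end of a gene took the place of its transcription start site.

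Read counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr by group, TMM normalisation and the robust quasi-likelihood F test. Genotypes were compared within each stage in a fit of that stage's 9 libraries. Stages, and the difference of a genotype's effect between stages (interaction), were compared in a fit of all 18. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested, 12188 in pre-pro B cells, 11411 in pre-B cells and 12440 across both. Biological coefficients of variation were 8.13%, 16.3% and 12.4%. Expression levels are TMM-normalised CPM, as mean ± SD of 3 libraries, and log2 fold changes carry their standard error. Where a group had no counts, the fold is a lower bound against a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio of pooled counts is given with its 95% counting interval. Such intervals and floors cover counting error only. On simulated counts with 200 changed genes per contrast, the homo against WT test recovered 57.6%, 84.8% and 92.6% of changes of 1.5, 2 and 4 fold in pre-pro B cells (12091 genes in the step). In pre-B cells it recovered 18.3%, 73.3% and 93.9% (11267 genes), and 2.78% and 4.7% of the calls were false. The cell cycle list was also shifted by log2 1 in these draws, and its genes count among the calls. The draws held no sex difference and no counts that level off with depth, so these shares are not error rates of the real calls.

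The 19 gene lists covered B lineage transcription factors, pre-B and B cell receptor signalling, V(D)J recombination, mature B and plasma cell markers, and stem and multipotent progenitor genes. They also covered IL-7 and JAK-STAT signalling, cell cycle, adhesion and integrin signalling, glucose uptake and glycolysis, and markers of T lineage, myeloid, plasmacytoid dendritic, NK and innate lymphoid, erythroid and megakaryocyte, and stromal and endothelial cells. The remaining lists were Notch targets, interferon response, immediate early and heat shock genes, and apoptosis and p53 targets. Each list with at least 5 tested members was tested two-sided with camera (limma 3.58.1, correlation preset at 0.01), adjusted over the lists of a contrast. Camera with an estimated correlation and fry were run beside it. The groups, comparisons, tests, gene lists and the rule for naming genes were fixed before the data were examined. By that rule, up to 10 genes with the largest rises and 10 with the largest falls could be named per contrast with WT, and 5 each for other contrasts. They had to be called, with a mean of at least 5 CPM in the higher group and no overlap between replicates (not asked of interactions). Up to 4 members per list with the lowest adjusted p were also eligible, as were the Ikaros family genes, the 5 peaks of highest fold per list and the peaks within 10 kb of eligible pre-B genes. Receptor gene segments and genes known only by a clone name were left out. The text gives a part of the eligible genes and peaks, and some items are not reported here.

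Peaks were compared in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6, and plots were drawn with matplotlib 3.10.9. A peak counted as overlapped when it shared at least 1 bp with a peak of the other list, and the overlap code was checked against a direct search (150 of 150 intervals equal). Shares carry 95% Wilson intervals. Overlaps are set beside the mean of 1000 random placements of the peaks within their chromosomes. With 1 library per list no test between genotypes was made, and the intervals do not cover the spread between animals. Genes near peaks were compared with genes called in pre-B cells by Fisher's exact test, two-sided, against tested genes that were not called.

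Alternatives planned for the RNA comparisons were DESeq2 size factors, no count filter, a stricter filter (1 CPM in 6 libraries), and the DESeq2 1.42.0 Wald test. All 18 or only the 6 compared libraries, the replicate number as a block, and each replicate left out in turn were planned too. Other alternatives were chosen after the data were seen: a sex term, XX libraries only, log2 library size as a covariate, a minimum log2 fold of 1, a mouse block and the omission of the 2 shallowest pre-B libraries. So were the gene span and the expression strata for the genes near peaks. Xist and Ddx3y counts showed that all WT libraries came from XX mice, while het replicate 2 and homo replicates 1 and 3 were XY at both stages. The sexes show that the het and the homo samples came from at least 2 animals each. Whether every replicate, those of WT included, came from a separate animal is not stated, so part of the spread behind each p may be technical.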

Results

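RNA was sequenced from pre-pro B and pre-B cells of WT, het and homo mice, with 3 libraries in each of the 6 groups. In pre-pro B cells the libraries held 5443344, 6080563 and 6492192 gene counts in WT, 4683715, 8771793 and 8395882 in het and 9048055, 8592557 and 8938811 in homo. In pre-B cells they held 6187816, 5556696 and 6105813 in WT, 6358635, 4265056 and 6757040 in het and 6212714, 6257527 and 1888871 in homo. The first principal component, with 82.9% of the variance, parted the stages, and the next held 6.15%. Peak lists came from 8 ChIP libraries, 4 with the Ikaros antibody and 4 with the Aiolos antibody, from WT and homo pre-B cells and thymocytes.

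Ikzf3, the gene that carries the substitution, was low in pre-pro B cells and high in pre-B cells of every genotype. Its level in pre-pro B cells was 15.7 ± 2.45 CPM in WT, 23.8 ± 1.7 in het and 16.2 ± 1.57 in homo, and in pre-B cells 539 ± 17.7, 540 ± 57.5 and 522 ± 80.7. Ikzf2, encoding the family member Helios, stood at 85 ± 6.59, 93.1 ± 7.65 and 87 ± 6.37 CPM in pre-pro B cells and at 1.59 ± 0.339, 1.44 ± 0.721 and 2.34 ± 1.33 in pre-B cells. Ikzf1 stood at 677 ± 24.5, 607 ± 65.7 and 556 ± 9.84 CPM in pre-pro B cells and at 784 ± 27.8, 846 ± 99.4 and 943 ± 275 in pre-B cells. In homo pre-pro B cells Ikzf1 fell by 0.30 ± 0.08 on the log2 scale (adjusted p = 0.0236). That call was lost without WT replicate 1 (0.119) or 2 (0.0954) or homo replicate 1 (0.0715), 2 (0.0718) or 3 (0.0603), and over 16 alternatives the adjusted p ran from 0.000483 to 0.289. The Ikzf3 difference between het and WT pre-pro B cells was not called (log2 0.59 ± 0.13, adjusted p = 0.0558), nor was that between homo and WT pre-B cells (−0.05, adjusted p = 0.853). The substitution changes an amino acid, so these counts do not check the genotype labels.

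The stage contrast asked how pre-B cells differ from pre-pro B cells of the same genotype. In WT, pre-B cells had higher levels of the B lineage regulators Pax5 (from 11 to 207 CPM, 18.7-fold), Bach2 (11.2-fold) and Irf4 (8.59-fold) and of Ikzf3 (34.1-fold). Genes that cut and join receptor segments rose: Rag1 from 113 to 1060 CPM (log2 3.24 ± 0.23, adjusted p = 1.06e-09), Rag2 13.6-fold and Lig4 13.2-fold. The surface marker gene Ms4a1 (93.5-fold), the cell cycle genes Cdk1 (5.85-fold) and Ccne1 (5.44-fold) and the integrin gene Itga6 (15.8-fold) rose too. Fam189a1 and Shank2, with no counts in WT pre-pro B cells, were at least 129-fold and at least 111-fold higher.

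Several genes typical of plasmacytoid dendritic cells and of other lineages were much lower in WT pre-B than in WT pre-pro B cells, though 3 T lineage and 2 myeloid list members rose. Siglech fell from 694 ± 58.6 to 0.327 CPM (log2 −10.95 ± 0.31, adjusted p = 4.28e-15) and Runx2 from 1160 to 0.807 CPM (1360-fold). Flt3, a receptor gene of early progenitors and dendritic cells, was 298-fold lower, and Ly6a 41.7-fold, Ikzf2 52.4-fold, Notch3 396-fold and Ccr2 521-fold lower. Cd4 fell from 523 ± 30.7 CPM to 3 counts in all (pooled ratio 3060, interval 1050 to 14800) and Cdh1 from 354 CPM to 1 count (pooled ratio 6240, 1120 to 246000). No counts were left in pre-B cells for Chdh (at least 3610-fold lower), Cd8a (at least 789-fold), Cebpa (at least 398-fold) and Klrk1 (at least 94.1-fold). Of 12440 genes, 3851 rose and 4146 fell in WT, 4025 and 4452 in het, and 4063 and 4531 in homo. The 26 genes named for this WT contrast were called under every alternative that tested them. The stricter count filter tested 25 of them.

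By list, all 14 stem and multipotent progenitor genes tested fell in WT pre-B cells (median log2 −3.83, adjusted p = 6.87e-07, 0.00204 with an estimated correlation), as did 19 of 20 plasmacytoid dendritic cell genes (median −5.92, adjusted p = 2.88e-11, 0.0235 with an estimated correlation). Members that rose were 16 of 20 B lineage transcription factors (adjusted p = 7.87e-06, 0.165 with an estimated correlation), 15 of 20 receptor signalling genes (3.34e-05, 0.182), 10 of 14 V(D)J recombination genes (0.00175, 0.104) and 29 of 30 cell cycle genes (1.31e-10, 0.218). Members that fell were 13 of 17 NK (adjusted p = 0.000147, 0.238 with an estimated correlation), 13 of 21 adhesion (0.00854, 0.104), 12 of 18 T lineage (0.0252, 0.165), 9 of 17 myeloid (0.00854, 0.191) and 14 of 20 interferon response genes (0.00453, 0.508). Adjusted over the list alone, the counts of members called were the same for every list but the immediate early genes (0 rose and 3 fell, against 1 and 4 over all genes). Lists not called in WT were glucose uptake (adjusted p = 0.0597), mature B (0.819), IL-7 (0.819), Notch targets (0.795), erythroid (0.795, 1 rose and 1 fell of 5), stromal (0.185), immediate early (0.891) and apoptosis genes (0.981). The erythroid list had a median of 0 beside an upward test. The IL-7 list's median of 0.0568 and the mature B list's mean of 0.15 were above 0 beside downward tests, and the apoptosis list's median of −0.208 was below 0 beside an upward one. In homo the call of the interferon list was lost without pre-B homo replicate 2 (adjusted p = 0.0668), and over 16 alternatives it ran from 0.000511 to 0.6.

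Homo and WT pre-pro B cells were compared to ask what the substitution on both copies changes at the earlier stage. Genes of cytotoxic lymphocytes were much higher in homo cells: the granzyme gene Gzmb rose from 0.318 ± 0.311 to 49.9 ± 12.7 CPM (log2 7.13 ± 0.58, adjusted p = 0.000792), Gzma from 1.6 ± 0.994 to 51.7 ± 10.6 (31.2-fold) and the NK receptor gene Ncr1 from 1 ± 0.214 to 18.1 ± 6.31 (17.5-fold). The NK receptor genes Klra3 (pooled ratio 60.3, 16.5 to 502), Klra9 (21.5-fold) and Klrk1 (2.84-fold) rose as well, as did Serpinb9b (pooled ratio 148, 26.4 to 5890), Itga2 (13.3-fold), Avil (39.2-fold), Rab44 (12.4-fold) and Zap70 (3.18-fold). Genes for granule proteases of myeloid progenitors rose: Ctsg from 0.222 ± 0.0782 to 8.25 ± 2.22 CPM, Prtn3 from 2.25 ± 0.847 to 13.5 ± 2.02 and Elane from 0.263 ± 0.322 to 4.86 ± 0.605. The progenitor genes Kit (34.1 ± 2.69 to 72 ± 8.57 CPM, 2.09-fold) and Cd34 (4.86-fold), the cell cycle genes Ccne1 (2.46-fold) and Mcm4 (1.44-fold), and Bcl2 (1.93-fold) were also higher.

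The joining chain gene Jchain fell from 108 ± 38 CPM in WT to 3.67 ± 0.544 in homo pre-pro B cells (29.7-fold lower, log2 −4.89 ± 0.38, adjusted p = 0.00111), and stood at 148 ± 33.4 in het. Adamtsl2 fell from 78.2 ± 12.1 to 25.2 ± 3.34 CPM (3.13-fold), and C8a (5.05-fold), Cdhr1 (4.76-fold), Sardh (3.03-fold), Flt4 (2.89-fold) and Pkd2 (2.72-fold) were lower. Smaller falls were those of the innate sensor gene Tlr9 by 1.45-fold (416 ± 23.1 to 288 ± 18.2 CPM), of Notch3 by 1.56-fold, of Pik3ap1 by 1.45-fold and of Xbp1 by 1.41-fold. The abundant genes Actb (log2 −0.548), B2m (−0.547) and Eef1a1 (−0.508), whose raw counts hardly grew in the deeper homo libraries, fell about as far as Tlr9, Pik3ap1 and Xbp1. With library size as a covariate the log2 change was −0.36 for Tlr9, no longer called, and −0.28 for Pik3ap1 and −0.23 for Xbp1, both called. Of the 34 genes named for this contrast, 12 stayed called with that covariate. The 24 NK and myeloid list genes called higher had a median log2 fold of 2.24 with it, against 2.99 without. All 24 stayed higher, and 6 stayed called. Gbp10 (3.09-fold, adjusted p = 0.0154), Tnf (2.81-fold, 0.0149) and Ifi44 (2.71-fold, 0.0324) were lower as called with all libraries. Their calls were lost without WT replicate 1 (Ifi44 0.066), WT replicate 2 (Gbp10 0.0558, Tnf 0.0506, Ifi44 0.0914), WT replicate 3 (Ifi44 0.0732), homo replicate 2 (Gbp10 0.0616, Ifi44 0.0999) or homo replicate 3 (Tnf 0.0584, Ifi44 0.104). Over 16 alternatives their adjusted p reached 0.172, 0.218 and 0.279, from lows of 9.83e-05, 7.76e-05 and 0.000876.

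In all, 2730 of 12188 genes were called between homo and WT pre-pro B cells, 1467 higher and 1263 lower. With library size as a covariate 213 were called (99 higher, 114 lower) and with a sex term 605 (440 and 165). XX libraries alone held no homo library but replicate 2, so no count is given for them. Most changes were small, since 445 of the higher and 65 of the lower genes had a log2 fold of at least 1. The count was 1112 without WT replicate 1, 1231 without WT replicate 2, 1226 without homo replicate 2 and 1378 without homo replicate 3. The homo libraries were deeper (8592557 to 9048055 counts) than the WT libraries (5443344 to 6492192), and 2 of the 3 came from XY mice while every WT library came from XX mice.

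**Figure D1:**
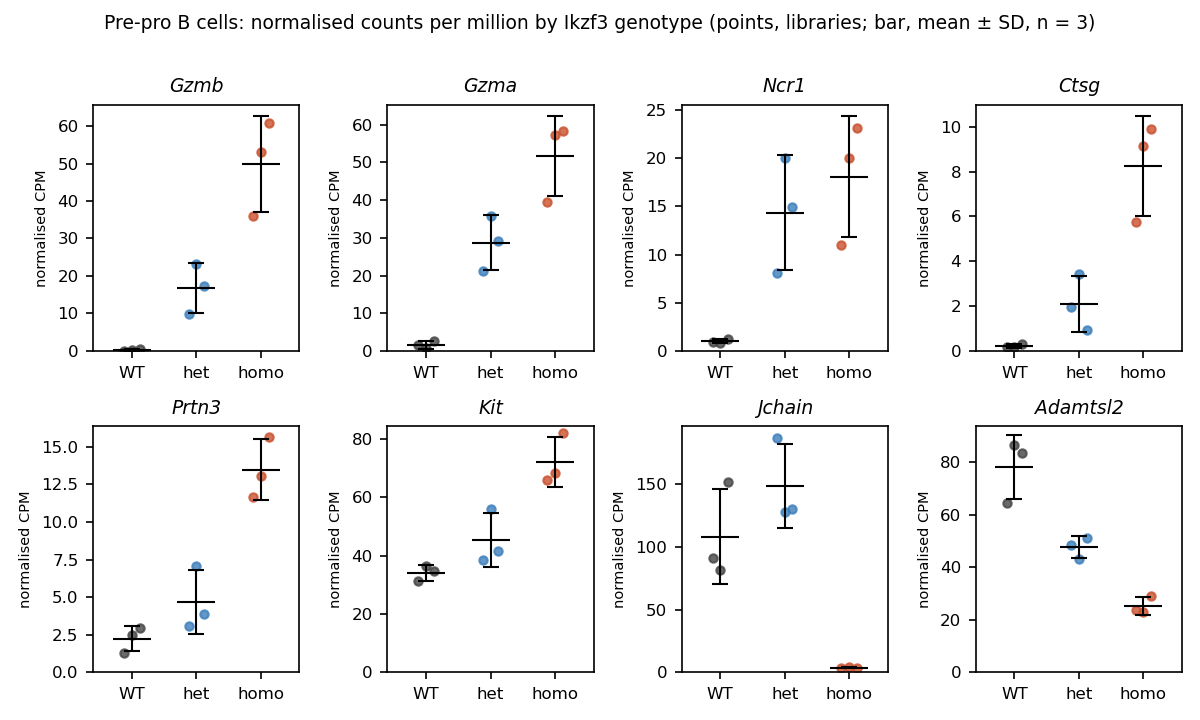
Normalised CPM of 8 genes in the pre-pro B libraries, by Ikzf3 genotype; points are libraries, bars are mean ± SD of 3. Gzmb ran from 0.318 in WT through 16.8 in het to 49.9 in homo, whereas Jchain was low in homo alone, at 3.67.

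By list, 25 of 30 cell cycle genes rose in homo pre-pro B cells (27 adjusted over the list alone, median log2 1.22, adjusted p = 5.52e-11, but 0.541 with an estimated correlation). Of the NK and innate lymphoid genes, 14 of 17 rose (14 adjusted over the list alone, median 2.41, adjusted p = 4.66e-09, 0.541 with an estimated correlation), and of the myeloid genes 10 of 19 (12 higher and 2 lower adjusted over the list alone, median 1.78, 9.37e-05, 0.541 with an estimated correlation). Plasmacytoid dendritic cell genes were lower (8 of 20 fell, 18 adjusted over the list alone, median −0.496, adjusted p = 8.24e-08, 0.541 with an estimated correlation), as were interferon response genes (10 of 20 fell, 14 adjusted over the list alone, median −1.04, 1.25e-07, 0.541 with an estimated correlation). The homo libraries with these shifts were also the deeper ones.

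The other lists were not called between homo and WT pre-pro B cells. Mature B genes came nearest (1 rose and 3 fell of 16, adjusted p = 0.0608). B lineage transcription factors had 3 higher and 4 lower members (0.816), receptor signalling genes 1 and 7 (0.378), adhesion genes 7 and 6 (0.848), T lineage genes 6 and 3 (0.556), glucose uptake genes 2 and 4 (0.544) and stem and progenitor genes 5 and 2 (0.582). Notch targets had 2 higher and 3 lower members (0.634), immediate early genes 0 and 3 (0.443), V(D)J genes 2 and 0 (0.582), IL-7 genes 2 and 0 (0.816), apoptosis genes 1 and 0 (0.656) and stromal genes 1 and 0 (0.582). The receptor signalling list (median 0.151, mean 0.0362) and the Notch targets (median 0.00114) lay above 0 beside a downward test, as did the mean of the immediate early list (0.153).

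In het pre-pro B cells, with 1 copy changed, the cytotoxic genes were higher than in WT by smaller folds: Gzmb 49-fold (to 16.8 ± 6.67 CPM, log2 5.62 ± 0.68, adjusted p = 0.0247), Gzma 17.7-fold, Ncr1 14.4-fold and Nkg7 5.73-fold. Id2, a regulator of innate lymphoid cells, rose from 11.5 ± 1.1 to 25.8 ± 4.96 CPM. Adamtsl2 (1.66-fold), Notch3 (1.39-fold) and Maged1 (1.31-fold) were lower. With all libraries 68 genes were called by edgeR, 53 higher and 15 lower, 466 by DESeq2, and 2505 had an unadjusted p under 0.05. The edgeR count was 0 without WT replicate 1 (1791 at an unadjusted p under 0.05) or WT replicate 2 (1673). It was 444 without WT replicate 3, 1901 without het replicate 1 and 7 without het replicate 2. Of the 8 genes just named, 2 stayed called without het replicate 2 (lost: Gzmb 0.0652, Ncr1 0.0792, Nkg7 0.124, Id2 0.137, Adamtsl2 0.113, Notch3 0.0599) and 5 without het replicate 3 (lost: Ncr1 0.052, Nkg7 0.0726, Id2 0.0741). Without WT replicate 1 their adjusted p ran from 0.096 to 0.162, without WT replicate 2 from 0.0659 to 0.192, and over all alternatives from 1.13e-28 to 0.236.

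Het lists that moved were the cell cycle (1 of 30 rose, 27 adjusted over the list alone, median log2 0.934, adjusted p = 2.81e-14), NK (5 of 17 rose, 14 adjusted over the list alone, median 2.26, 2.07e-11), plasmacytoid dendritic (median −0.237, 7.21e-05), interferon (median −0.503, 7.21e-05), immediate early (median −0.291, 0.000923), T lineage (median 0.644, 0.0111) and myeloid (median 1.08, 0.0296) lists. Each had adjusted p = 0.604 with an estimated correlation. Adjusted over the list alone, 1 plasmacytoid dendritic and 1 immediate early gene fell, 7 T lineage genes rose and 1 fell, and 1 myeloid gene rose. The myeloid call was lost without WT replicate 3 (0.0705), het replicate 1 (0.0551) or het replicate 2 (0.0761), and over 17 alternatives its adjusted p ran from 0.000142 to 0.82. Without het replicate 2 the medians were 0.62 for myeloid, −0.106 for plasmacytoid dendritic and −0.177 for interferon genes. The plasmacytoid dendritic median was −0.45 without het replicate 1, and the immediate early median −0.192 without WT replicate 1. Of the lists not called, adjusted p ran from 0.101 to 0.951.

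Between homo and het pre-pro B cells only Jchain (40-fold lower in homo, log2 −5.32 ± 0.37, adjusted p = 0.0163) and Reln (from 6.39 ± 0.943 to 1.02 ± 0.257 CPM, 6.1-fold, adjusted p = 0.0186) were called by edgeR with all 9 libraries. Both calls were lost without het replicate 1 (0.0815 each), homo replicate 2 (0.182 and 0.215) or homo replicate 3 (0.0914 each). Over 16 alternatives the adjusted p of Jchain ran from 3.03e-55 to 0.182 and that of Reln from 1.24e-06 to 0.215. With all libraries 1470 genes had an unadjusted p under 0.05, and DESeq2 called 45. The edgeR count was 0 without het replicate 1, homo replicate 2 or homo replicate 3, with 1258, 906 and 922 genes at an unadjusted p under 0.05. It was 223 without het replicate 2, 4 without het replicate 3 and 13 without homo replicate 1. Lists higher in homo than het were myeloid (median 0.573, 10 rose adjusted over the list alone, adjusted p = 2.83e-06, 0.598 with an estimated correlation), NK (0.363, 4 rose adjusted over the list alone, 0.00482, 0.768 with an estimated correlation) and cell cycle genes (0.266, 0.0146, 0.849 with an estimated correlation). Plasmacytoid dendritic (−0.269, adjusted p = 3.75e-05, 0.768 with an estimated correlation) and interferon genes (−0.458, 5.13e-05, 0.768 with an estimated correlation) were lower. Calls were lost without het replicate 1 (cell cycle 0.093, NK 0.093, plasmacytoid dendritic 0.131, interferon 0.0512), het replicate 3 (cell cycle 0.332) or homo replicate 3 (cell cycle 0.105, NK 0.125). Without het replicate 1 the medians were −0.053 for plasmacytoid dendritic, −0.226 for interferon and 0.17 for NK genes, and without homo replicate 3 that of NK genes was 0.0859. Without het replicate 2 they were 0.429 for cell cycle, 1.15 for myeloid, 0.659 for NK and −0.802 for interferon genes. Without het replicate 3 they were 0.92 for myeloid and −0.276 for interferon genes, without homo replicate 1 0.655 for NK and without homo replicate 2 1.01 for myeloid genes. Over 17 alternatives these adjusted p values reached at most 0.849.

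Het and homo changes in pre-pro B cells went the same way. Of the 68 genes called in het, 67 were called in homo in the same direction (53 higher and 14 lower), where independent lists of these sizes would share 6.38 and 1.55. In 20 simulations all 9 libraries, WT included, were drawn anew from the WT means, with het and homo unchanged. The mean overlap was then 0.1 and the highest 1. These draws held no sex difference and no counts that level off with depth, so they do not measure what those add. In the data the overlap was 7 with a sex term. Homo replicate 2 was the only XX homo library, so no overlap is given for XX libraries alone. The correlation of the log2 folds across genes was 0.862, against 0.55 in the simulations, and genes are not independent replicates. The overlap was 0 without WT replicate 1 or 2, 434 without WT replicate 3, 1690 without het replicate 1, 7 without het replicate 2, 5 without homo replicate 2 and 29 without homo replicate 3. All comparisons shared the 3 WT libraries, which are too few to be split, so part of the excess may come from the shared controls.

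**Figure D2:**
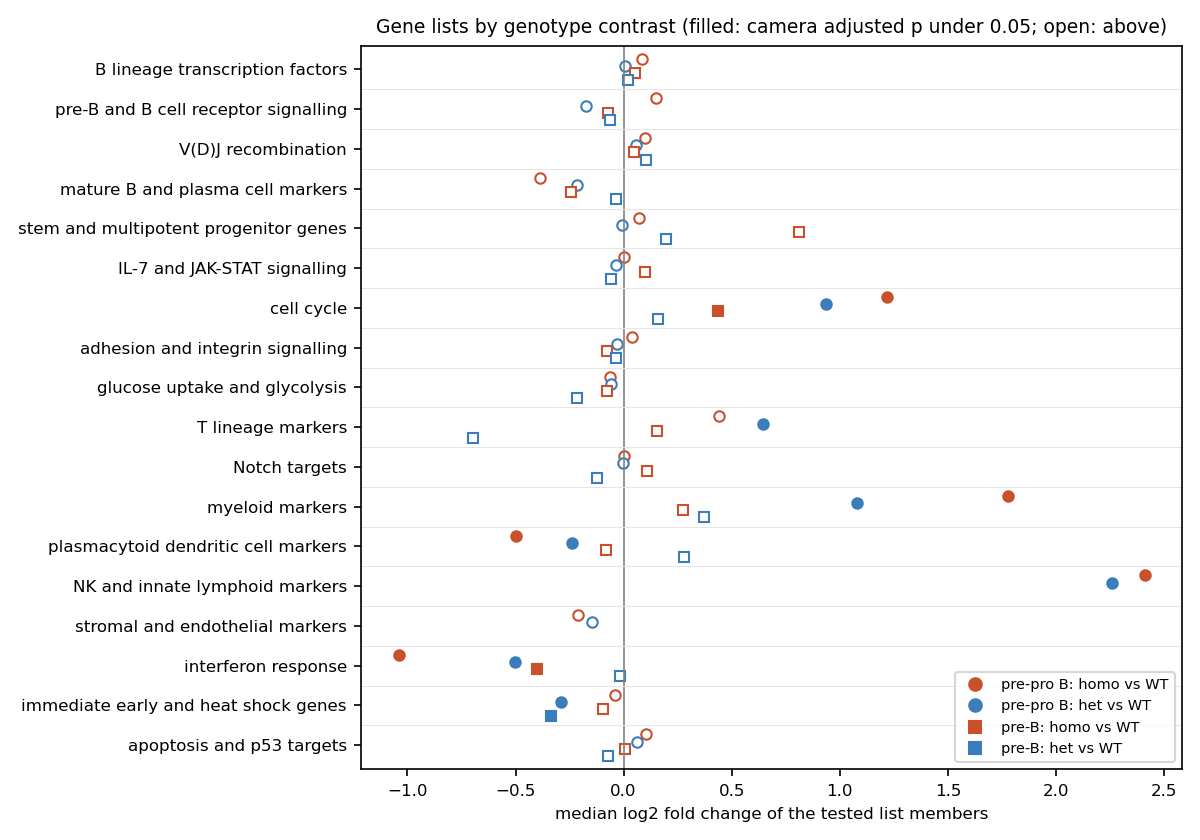
Median log2 fold change of the tested members of each gene list, for het and homo against WT in pre-pro B (circles) and pre-B cells (squares); filled symbols have a camera adjusted p under 0.05 at the preset correlation. In pre-pro B cells the NK list lay at 2.41 in homo and 2.26 in het.

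Pre-B cells express Ikzf3 at a high level, and homo and WT cells were compared there for the effect of both changed copies. Prdm1, encoding the plasma cell regulator Blimp-1, rose from 14.9 ± 1.31 to 197 ± 50.4 CPM in homo cells (13.2-fold, log2 3.72 ± 0.19, adjusted p = 6.54e-06). The semaphorin gene Sema4g rose from 2.15 ± 0.349 to 127 ± 43 CPM (59.3-fold) and Rasd1 from 2.6 ± 0.556 to 69.6 ± 17.5 (26.8-fold). The cytokine receptor gene Il9r (64.1-fold), the catenin gene Ctnnd1 (4.33-fold), the chemokine gene Ppbp (at least 55.1-fold), the B cell receptor modulator Cd22 (1.75-fold), Satb1 (log2 0.97 ± 0.14), Socs2 (2.28-fold), the fibronectin gene Fn1 (3.58-fold) and Tyms (1.53-fold) rose. Higher too were Pamr1 (pooled ratio 149, 26.3 to 5940), C4bp (144, 25.4 to 5740), Olfm1 (92.6, 25.2 to 772), Thbs1 (37.5-fold), Etl4 (30.6-fold) and the heat shock gene Hspa1b (15.3-fold). Hspa1a was called higher (pooled ratio 37.3, 9.88 to 315, adjusted p = 0.0191), but not without WT replicate 1 (0.0729), 2 (0.0584) or 3 (0.0621), and over 16 alternatives its adjusted p ran from 0.00012 to 0.147.

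Members of the mature B list moved both ways in homo pre-B cells (4 rose and 6 fell, list adjusted p = 0.428), and Cd22 rose. Tnfrsf13c, encoding the BAFF receptor, fell from 140 ± 3.45 to 24.5 ± 4.74 CPM (5.57-fold), the IgE receptor gene Fcer2a from 20.9 ± 4.18 to 0.21 ± 0.242 (70.3-fold) and Ms4a1 from 117 to 38 (2.99-fold). Polm, encoding a polymerase of end joining, fell from 287 ± 16.9 to 36 ± 10.4 CPM (7.66-fold), and the catenin gene Ctnna1 from 149 ± 4.74 to 28.2 ± 3.5 (5.32-fold). The collagen gene Col5a3 fell from 421 ± 82.3 to 3.9 ± 0.331 CPM (110-fold, log2 −6.78 ± 0.38, adjusted p = 8.5e-06) and Fmn2 from 111 ± 4.82 to 1.08 ± 0.56 (88.6-fold). Shank2 fell from 18.2 ± 1.38 CPM to no count (at least 88.2-fold lower). The regulators Id3 (3.78-fold), Bcl11a (2.04-fold) and Spib (1.68-fold), the interferon-induced Mx1 (15.6-fold) and Mx2 (24.7-fold), and Fos (5.68-fold), Btg2 (2.89-fold), Sdc1 (7.81-fold) and Lgals1 (3.64-fold) were lower. So were Il6ra (pooled ratio 59.5, 20.1 to 291), Col25a1 (67, 22.7 to 327), Galnt10 (36.8-fold), Zscan12 (30.5-fold), Ceacam1 (30.1-fold), Etnk2 (28.6-fold), Hk1 (2.75-fold), Insr (1.77-fold) and Pik3ap1 (1.69-fold).

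Between homo and WT pre-B cells 1811 of 11411 genes were called, 847 higher and 964 lower, of which 381 and 539 had a log2 fold of at least 1. The count was 1055 without WT replicate 1, 1068 without WT replicate 2 and 1157 without WT replicate 3. It was 3456 with library size as a covariate and also 3456 without the 2 shallowest pre-B libraries. In the shallowest, homo replicate 3, Actb stood at 900 CPM, against 385 and 370 in homo replicates 1 and 2. Homo means and SDs of abundant genes therefore carry the level of that library. Of the 44 genes named for this contrast, every one but Hspa1a stayed called whichever single library was left out.

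**Figure D3:**
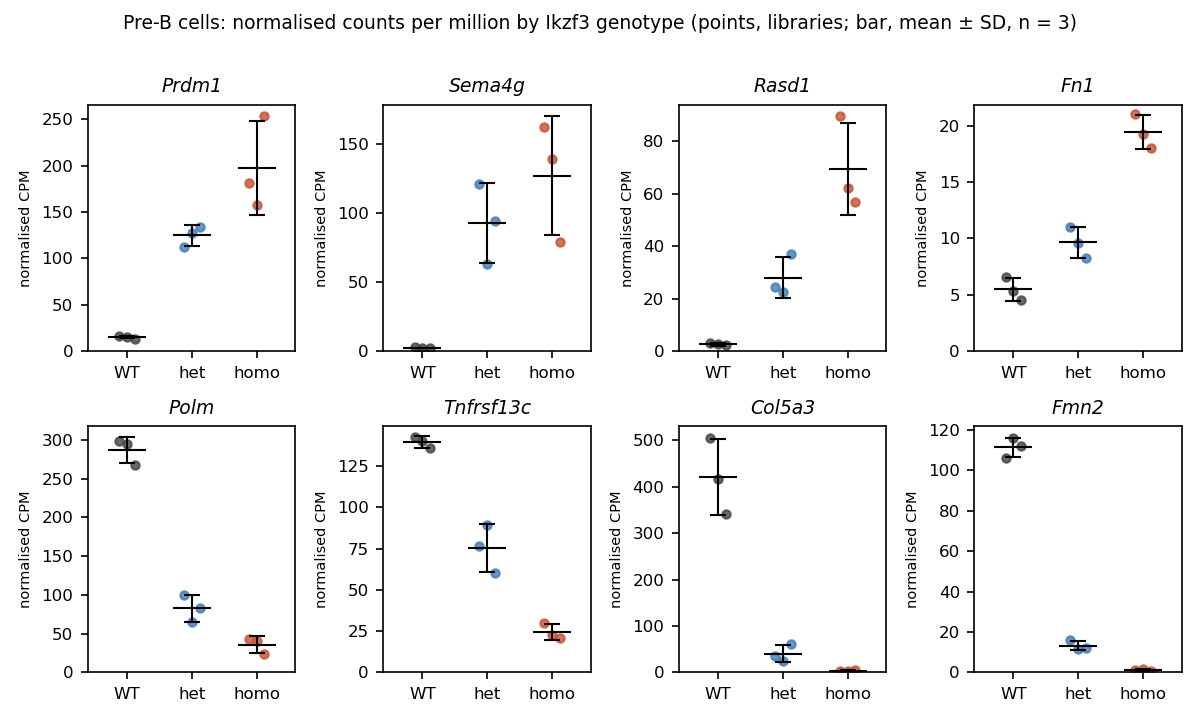
Normalised CPM of 8 genes in the pre-B libraries, by Ikzf3 genotype; points are libraries, bars are mean ± SD of 3. Prdm1 stood at 14.9 in WT, 125 in het and 197 in homo, and Col5a3 at 421, 40.3 and 3.9.

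Few lists moved as a whole in homo pre-B cells. Cell cycle genes were higher (4 of 30 rose, 4 adjusted over the list alone, median log2 0.437, adjusted p = 5.31e-05, 0.987 with an estimated correlation). Interferon response genes were lower (6 of 20 fell and 1 rose, the same adjusted over the list alone, median −0.399, adjusted p = 0.0325, 0.987 with an estimated correlation). Without homo replicate 3 the cell cycle median was 0.191. The interferon call was lost without homo replicate 2 (median −0.254, adjusted p = 0.273) or homo replicate 3 (−0.225, 0.101), and over 18 alternatives the adjusted p ran from 0.00172 to 0.987. Members of other lists moved both ways: 4 mature B genes rose and 6 fell (adjusted p = 0.428), 6 adhesion genes rose and 3 fell (0.986), 4 stem and progenitor genes rose and 1 fell (0.16), 2 B lineage transcription factors rose and 4 fell (0.771), and 2 immediate early genes rose and 5 fell (0.428). Glucose uptake (0.428), myeloid (0.428), Notch (0.729), receptor signalling (0.746), V(D)J, IL-7, T lineage, plasmacytoid dendritic and apoptosis lists (0.986) were not called either. Median and test differed in sign for the B lineage (median 0.0522, mean −0.124), V(D)J (0.0471, −0.0527), T lineage (0.153), adhesion (−0.0765) and apoptosis lists (0.00515).

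Het pre-B cells, with 1 changed copy, shared many of these changes. Prdm1 was 8.34-fold higher than in WT (125 ± 11 CPM, log2 3.06 ± 0.19, adjusted p = 5.98e-05), Sema4g 42.6-fold, Il9r 56.1-fold, Kcnj1 42.9-fold, Slc47a1 23.8-fold and Rasd1 10.7-fold. Smoc1 rose from 10.3 ± 3.99 to 99.3 ± 24.2 CPM and the costimulatory gene Cd86 from 4.83 to 17.5 ± 7.56. Arhgef39 fell from 49.8 ± 2.54 to 3.54 ± 1 CPM, and Shank2 (72.8-fold), Fam101a (pooled ratio 34.7, 11.6 to 171), Zscan12 (16.7-fold), Col5a3 (10.4-fold), Id3 (4.63-fold), Polm (3.48-fold) and Lef1 (from 163 to 81.9 CPM) were lower. There were 705 genes called, 319 higher and 386 lower. The count was 336 without WT replicate 1, 341 without WT replicate 2, 338 without WT replicate 3 and 355 without het replicate 1. It was 3005 with library size as a covariate and 1716 without the 2 shallowest pre-B libraries. All 16 genes named here stayed called in each of those fits. In het replicate 2, the shallowest het library, Actb stood at 495 CPM, against 371 and 364 in het replicates 1 and 3. Het means and SDs of abundant genes carry the level of that library.

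The only list called in het pre-B cells was the immediate early and heat shock genes (3 of 19 fell, 3 lower and 1 higher adjusted over the list alone, median log2 −0.335, adjusted p = 0.0441, 0.729 with an estimated correlation). That call was lost without het replicate 1 (0.0598) or het replicate 2 (median −0.21, adjusted p = 0.073), and over 18 alternatives it ran from 0.0141 to 0.729. Adjusted p of the other lists ran from 0.0937 to 0.958.

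Homo pre-B cells differed from het cells in the depth of several shared changes. Fcer2a was 26.1-fold lower in homo (log2 −4.71 ± 0.58, adjusted p = 0.00446), Fmn2 10.6-fold (0.00192), Col5a3 10.6-fold (0.00315) and Tnfrsf13c 2.98-fold (0.00315). Olfm1 rose from 0.99 ± 0.4 to 10.6 ± 0.874 CPM, the interferon-induced Iigp1 from 6.84 ± 4.46 to 52.6 ± 11.9, and Hemgn 7.23-fold. Tead1 (8.18-fold, adjusted p = 0.0434) and Nrg2 (7.59-fold, 0.0274) were called higher and Tlr1 (6.44-fold, 0.0122) and Rgs13 (5.86-fold, 0.0111) lower. Those calls were lost without het replicate 1 (Tead1 0.143, Nrg2 0.0525, Tlr1 0.0598, Rgs13 0.0564), het replicate 2 (Tead1 0.0522, Nrg2 0.0585) or het replicate 3 (Tead1 0.0753, Nrg2 0.0986). They were also lost without homo replicate 1 (Tead1 0.0778, Nrg2 0.0681, Rgs13 0.0502) or homo replicate 2 (Tead1 0.097, Nrg2 0.131, Rgs13 0.0624). Over the alternatives their adjusted p reached 0.15 for Tead1, 0.131 for Nrg2, 0.087 for Tlr1 and 0.0624 for Rgs13.

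There were 216 genes called between homo and het pre-B cells, 92 higher and 124 lower. The count was 52 without het replicate 1, 137 without homo replicate 1, 66 without homo replicate 2 and 374 without homo replicate 3, the library of 1888871 counts. Mature B genes were lower in homo (2 of 17 fell, 6 adjusted over the list alone, median log2 −0.297, adjusted p = 0.000757, 0.359 with an estimated correlation). Higher were stem and progenitor genes (2 of 9 rose, 3 adjusted over the list alone, 0.368, 0.00855, 0.326 with an estimated correlation) and cell cycle genes (0.258, 2.12e-06, 0.607 with an estimated correlation). Without homo replicate 3 the cell cycle median was 0.0416 and the list was not called (adjusted p = 0.119). Interferon genes were lower (−0.274, adjusted p = 0.0362, 0.841 with an estimated correlation), but not without het replicate 1 (median −0.151, adjusted p = 0.564), het replicate 3 (0.0712), homo replicate 2 (0.303) or homo replicate 3 (0.113). The interferon median was −0.466 without het replicate 2 and −0.64 without homo replicate 1. The mature B median was −0.447 without homo replicate 1, and that of the stem list 0.602 and 0.605 without het replicates 2 and 3 and 0.569 without homo replicate 1. Over 18 alternatives the adjusted p of the interferon list ran from 6.84e-06 to 0.841 and that of the cell cycle list from 2.81e-08 to 0.607.

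Genes changed in both het and homo pre-B cells numbered 622 (277 higher and 345 lower), where independent lists would share 23.7 and 32.6 and the 20 simulations shared 0. The correlation of log2 folds across genes was 0.819, against 0.482 in the simulations. Of the 622, 124 had the larger change in het, and the median size was 1.19 in het and 1.6 in homo. The overlap was 303 without WT replicate 1, 313 without WT replicate 2, 315 without WT replicate 3, 339 without het replicate 1 and 1048 without homo replicate 3. The same limits from shared WT libraries and from the simulations apply.

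Whether homo cells lie further along the WT stage difference than het cells was asked with genes defined in WT libraries alone. The pre-B set held the 200 called genes with the largest rise from WT pre-pro B to WT pre-B cells. The pre-pro B set held the 200 with the largest fall. Of the pre-B set 184 were tested in pre-B cells. They shifted down in homo against het (median log2 −0.181, camera p = 1.52e-08, 0.0326 with an estimated correlation). Of them 124 lay below 0, 7 of these called by edgeR. Of the 200 genes of the pre-pro B set only 13 passed the count filter in het and homo pre-B cells. These 13 shifted up (median 0.546, camera p = 0.000109, 0.0149 with an estimated correlation). Of them 9 lay above 0 and 5 had an unadjusted p under 0.05 in edgeR, with 0 called. They are the members still detected in these cells and do not stand for the whole set. In pre-pro B cells the pre-B set of 97 shifted up in homo (median 0.25, p = 0.00189, 0.417 with an estimated correlation). Of it 66 lay above 0 and 19 of these had an unadjusted p under 0.05 in edgeR, but the 1 gene called was lower. The pre-pro B set of 200 shifted down (−0.13, p = 0.000149, 0.243 with an estimated correlation), with 144 below 0, 25 of these at an unadjusted p under 0.05 in edgeR and 0 called. With 1 library left out, the median of 0.546 ran from 0.695 to 1.06 (1.03 without het replicate 2, 1.06 without homo replicate 1, 0.854 without homo replicate 3). That range leaves out 0.546 itself. The count filter was rerun in each fit, so the members tested can differ. The median of −0.13 ran from −0.19 to −0.0733 (without het replicate 1). The median of 0.25 was 0.135 without het replicate 3 and 0.108 without homo replicate 3, and the set was not called in either case.

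The interaction asked whether a genotype's effect differs between the stages. The rise of Prdm1 in homo cells was larger in pre-B than pre-pro B cells by log2 3.10 ± 0.40 (adjusted p = 3.89e-05). The homo effect was lower in pre-B than pre-pro B cells for Polm (−2.65 ± 0.25, adjusted p = 1.47e-06), Ctnna1 (−2.49 ± 0.12, 1.81e-09), Fcer2a (−6.41 ± 0.65, 2.67e-06), Tnfrsf13c (−2.68 ± 0.27, 2.19e-06) and Mx2 (−3.99 ± 0.54, 5.56e-05). In het cells the effect was higher in pre-B cells for Sema4g (5.08 ± 0.74, adjusted p = 0.000401) and lower for Ctnna1 (−1.56 ± 0.12, 8.11e-07) and Arhgef39 (−4.38 ± 0.39, 2.74e-06). For homo, 1809 genes differed (643 with the higher effect in pre-B cells, 1166 with the lower), and for het 703 (230 and 473). With each replicate number of a genotype taken as 1 mouse in both stages, 1355 and 395 genes differed.

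In homo the interaction was called for the cell cycle (8 of 30 lower, 10 adjusted over the list alone, adjusted p = 0.00357, 0.899 with an estimated correlation), NK (0.00357, 0.835), myeloid (0.0452, 0.835) and plasmacytoid dendritic lists (0.0303, 0.835). Those calls were lost without pre-B homo replicate 2 (cell cycle 0.0603, plasmacytoid dendritic 0.0603, myeloid 0.121), and that of the myeloid list also without pre-pro B homo replicate 3 (0.0721) or pre-B WT replicate 1 (0.0665). In het the lists were cell cycle (adjusted p = 2.31e-07, 0.653 with an estimated correlation), NK (7.07e-07, 0.476), mature B (0.0374, 0.513), T lineage (0.0374, 0.476) and plasmacytoid dendritic (0.0374, 0.653). The mature B call was lost without pre-pro B WT replicate 2 (0.0625), pre-pro B het replicate 2 (0.15) or 3 (0.0591), pre-B WT replicate 3 (0.06) or pre-B het replicate 1 (0.0881). The T lineage call was lost without pre-pro B het replicate 3 (0.0759), pre-B het replicate 1 (0.0881) or 3 (0.12). That of the plasmacytoid dendritic list was lost without pre-pro B WT replicate 1 (0.068) or 2 (0.0564), pre-pro B het replicate 2 (0.255) or 3 (0.0723), pre-B WT replicate 2 (0.0722) or pre-B het replicate 1 (0.0881). Over 22 alternatives the highest adjusted p of these lists was 0.899.

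Ikaros peaks were compared between WT and homo cells to ask where Ikaros lies when Aiolos carries the substitution. In pre-B cells there were 3683 Ikaros peaks in WT (1433 kb, median fold 5.23) and 8609 in homo (3823 kb, median fold 4.78), and in thymocytes 3572 (1611 kb, 4.57) and 8221 (4392 kb, 4.26). Nearly all WT pre-B peaks were overlapped by a homo peak (3488, 94.7%, interval 93.9 to 95.4, against 0.324% at random), while 40.4% of homo peaks were overlapped by a WT peak (39.4 to 41.4) and 5132 were not. In thymocytes 78.9% of WT peaks (77.5 to 80.2) and 34.1% of homo peaks (33.1 to 35.1) were overlapped, and 5417 homo peaks were not. Of the homo-only pre-B peaks 741 (14.4%, 13.5 to 15.4, against 0.185% at random) were overlapped by a homo-only thymocyte peak. Read depth of the ChIP libraries is unknown, and each list is 1 library.

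Among the strongest 10% of the homo pre-B Ikaros peaks, 73 of 861 (8.48%, interval 6.8 to 10.5) had no WT overlap, against 0 of 368 for WT peaks (upper limit 1.03%). In thymocytes these were 215 of 822 (26.2%, 23.3 to 29.3) and 2 of 357. Of the 73, 72 (98.6%, 92.6 to 99.8) were overlapped by an Ikaros peak of homo thymocytes and 8 by one of WT thymocytes. A peak inside Prkce (chromosome 17, 86424843 to 86425567, fold 26.6) was in no WT list, and the Aiolos peak of highest fold in homo pre-B cells lay in it (86424982 to 86425437, fold 8.23). The highest homo pre-B folds were near Csnk1e (chromosome 15, 79461272 to 79463716, fold 35.7, 5693 bp from the gene) and inside Ddo (chromosome 10, 40645715 to 40647385, fold 29.2), and both regions also held an Ikaros peak of WT thymocytes. In WT thymocytes the highest fold was 37.9, at Snx29 (chromosome 16, 11685492 to 11688211). A peak's fold is the authors' own value.

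Aiolos peaks were few. In pre-B cells there were 431 in WT and 24 in homo, 5 of the WT peaks (1.16%) being overlapped by a homo one. In thymocytes there were 25 in WT and 184 in homo. Of the 431 WT pre-B peaks, 20 (4.64%, 3.02 to 7.06) were overlapped by a WT pre-B Ikaros peak. With a fold and −log10 q of at least 5, 19 of the 431 and 5 of the 24 were left, so the lists differ mostly in weak peaks. Of the 25 WT thymocyte peaks, 13 were overlapped by a WT thymocyte Ikaros peak. Of the 184 homo thymocyte peaks, 173 were overlapped by an Ikaros peak of homo thymocytes and 19 by one of WT thymocytes. In pre-B cells, 172 of them (93.5%, 88.9 to 96.2) were overlapped by a homo Ikaros peak and 6 by a WT one, and 149 (81%, 74.7 to 86) lay in the homo-only Ikaros sets of both cell types. Of the 24 homo pre-B Aiolos peaks, 21 were overlapped by a homo pre-B Ikaros peak and 5 by a WT one. The strongest Aiolos peak was near Tiam1 in WT pre-B cells (chromosome 16, 89905123 to 89905668, fold 7.84) and WT thymocytes (fold 10.6), and 14333 bp from Tagap in homo thymocytes (chromosome 17, 7910940 to 7911667, fold 15.7).

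**Figure D4:**
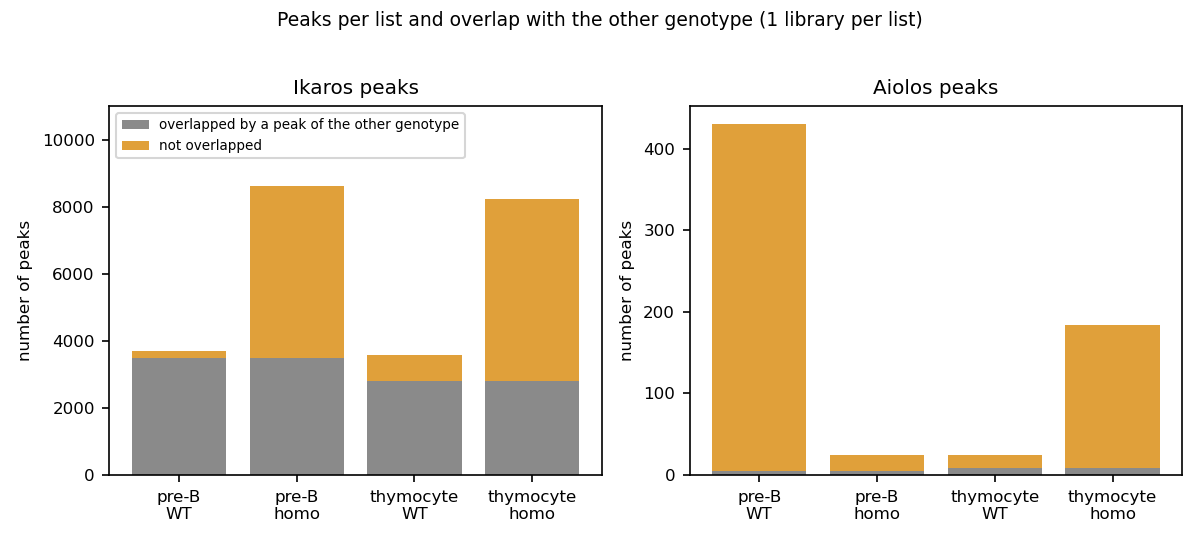
Number of Ikaros and Aiolos peaks per list, split by overlap of at least 1 bp with the list of the other genotype; each bar is 1 library. The homo Ikaros lists hold 8609 peaks in pre-B cells and 8221 in thymocytes, against 3683 and 3572 in WT.

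Genes changed in homo pre-B cells were compared with Ikaros peaks within 10 kb of either gene end, in the cultured pre-B cells of the ChIP assay. Genes that fell lay near WT peaks more often than uncalled genes (151 of 927, 16.3%, against 928 of 9219, 10.1%; odds ratio 1.74, 1.44 to 2.1, Fisher's exact adjusted p = 1.06e-07), near homo peaks (35.1%, odds ratio 1.72, 1.49 to 1.99, 2.49e-12) and near homo-only peaks (23%, 1.59, 1.35 to 1.87, 1.25e-07). Genes that rose lay more often near WT peaks (115 of 813, 14.1%, odds ratio 1.47, 1.19 to 1.81, adjusted p = 0.000732), but at 10 kb no excess was called near homo peaks (25.3%, odds ratio 1.08, 0.415) or homo-only peaks (14.8%, 0.924, 0.481). That depended on the setting. Near homo peaks the odds ratio was 0.963 at 2 kb, 1.27 at 50 kb (Fisher's exact adjusted p = 0.00164), 1.4 with stricter peaks (0.00268) and 1.62 over the gene span extended by 10 kb (4.8e-10). Near homo-only peaks it was 0.729 at 2 kb (0.048), 1.14 at 50 kb (0.0789), 0.94 with stricter peaks (0.84) and 1.47 over the span (9.52e-06). For genes that fell near homo-only peaks it was 1.22 with stricter peaks (0.31). Compared directly, at 10 kb alone, genes that fell lay more often than genes that rose near homo peaks (odds ratio 1.59, Fisher's exact adjusted p = 2.07e-05) and homo-only peaks (1.72, 2.07e-05); near WT peaks no difference was called (1.18, 0.23). Col5a3 had a homo peak and no WT peak within 10 kb (chromosome 9, 20762089 to 20762301, fold 3.87), as had Sema4g (chromosome 19, 44990188 to 44990544, fold 5.57), Olfm1 (chromosome 2, 28228290 to 28228557, fold 4.29) and Pamr1 (chromosome 2, 102541335 to 102541680, fold 4.01). Fcer2a had a WT peak (chromosome 8, 3674916 to 3675255, fold 4.65) and a homo peak (fold 5.17), and so had Ikzf1 (chromosome 11, 11678672 to 11679174, fold 7.25 in WT and 7.5 in homo). This search for single peaks took 42 of the pre-B genes eligible to be named, not all of them. Of the 42, 40 had coordinates and 13 had any such peak. Of uncalled genes 1455 of 9219 (15.8%) lay near a homo-only peak at 10 kb. Single genes with a homo peak and no WT peak therefore do not tie their change to the peak.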

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

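The tests that weigh explanations in the next 3 paragraphs were chosen only after the results were seen, while the interaction tests behind the values in the remaining paragraphs were planned.

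Plasmacytoid dendritic cell genes were lower in homo than in WT pre-pro B libraries, with a median log2 difference of −0.498 (interquartile range −0.546 to −0.424) and all 20 members lower. Counts that level off in deeper libraries cannot be told apart from a fall in the cells: lists matched on mean expression, though not on gene length, had a median of −0.129 (lowest of 10000, −0.288), but abundant genes outside the list fell as far as its members (Actb −0.548, B2m −0.547 and Eef1a1 −0.508, against −0.545 for the member Siglech), and the raw counts of the list grew by 0.139 where the libraries grew by 0.561. A lower share of plasmacytoid dendritic cells in the gate, which required B220, AA4.1 and CD43, may explain it as well: the more and the less abundant members fell alike (−0.462 and −0.504, difference 0.0411, permutation p = 0.35, two-sided). All 20 genes are expressed in these sorted cells, with Siglech at 694 CPM and Runx2 at 1160 in WT, so the list cannot separate a cell type from a cell state. Genotype and differences between libraries of 1 genotype cannot be told apart, since het replicates 2 and 3, deeper than het replicate 1, differed from it by −0.581 on the same list.

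NK and myeloid progenitor genes were higher in homo pre-pro B libraries, with a median log2 difference of 2.3 over 17 NK members (interquartile range 1.48 to 2.82) and 1.75 over 19 myeloid members (0.0768 to 2.93). For the NK genes the highest median of 10000 lists matched on mean expression was 0.785. Such lists did not capture the fall of abundant genes above, so they cannot exclude depth. A part may be depth. The NK list lay 0.997 higher in het replicates 2 and 3 than in the shallower het replicate 1 (interquartile range 0.555 to 1.13). Deeper homo libraries are argued against as the whole cause for these genes. That het step in depth was log2 0.874, while homo exceeded WT by only 0.561 in depth. Het replicate 1, shallower than each WT library, also lay 1.34 above WT on the list, though it is 1 library. For the myeloid genes depth cannot be told apart from genotype, since the highest matched median of 0.664 lay within the spread of the members. A larger share of 1 admixed cell population of fixed makeup might be the source, but this cannot be told apart from changes within cells: the homo to het folds of 14 NK members varied with a Cochran Q per degree of freedom of 2.11 between few libraries. The most abundant of these genes stood at 51.7 CPM (Gzma) and 49.9 CPM (Gzmb), the ratio of Gzmb to Ncr1 was 1.18 ± 0.0347 in het and 2.84 ± 0.359 in homo; the gate required B220, AA4.1 and CD43, so cells lacking any of these should have been left out.

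Ikaros lists of homo cells held many peaks that no WT peak overlapped. A few regions that differ between strains are argued against as the cause for the strongest peaks. The 73 of the strongest 10% in pre-B cells with no WT overlap lay on 19 chromosomes with at most 7 on one. This spread does not speak to differences scattered over the genome, and no input values were at hand to check them. A deeper or more efficient homo library cannot be told apart from other binding for these, as each genotype has 1 library of unknown depth, although in lists of equal length 8.42% of the strongest 10% in homo (6 to 11.7) and 0.272% in WT (0.048 to 1.52) lacked an overlap. For the other homo-only peaks a deeper library may account for them, as the median fold outside the strongest 10% was 4.23 for homo-only and 6.03 for shared peaks. Binding sites particular to homo cells may account for part, as 81% of the homo thymocyte Aiolos peaks lay in the homo-only Ikaros sets of both cell types. But each list is 1 library without a replicate. Recurrence in both cell types also does not set binding apart from a difference in the DNA of the animals.

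The homo effect differed between pre-B and pre-pro B cells in 1809 genes, and in 40 of the 77 tested genes named above for homo against WT; each value is the log2 effect in pre-B minus that in pre-pro B cells. Where a group had no or few counts the fitted value depends on the prior count and is no bound, as for Shank2 (−11.43), Flt4 (6.25), Avil (−6.71), Rab44 (−5.51), Pamr1 (6.85), Olfm1 (4.58) and Il6ra (−5.82). The effect was higher in pre-B cells for Jchain (3.49), Ifi44 (2.52), Xbp1 (1.08), Il9r (5.73), Sema4g (5.67), Thbs1 (5.69), Etl4 (6.05), Prdm1 (3.1), Ctnnd1 (1.31) and Satb1 (0.69). It was lower in pre-B cells for Ccne1 (−1.03), Tlr9 (−1.89), Zap70 (−1.46), Bcl2 (−1.36), Fmn2 (−5.13), Fcer2a (−6.41), Galnt10 (−5.14), Zscan12 (−5.02), Ceacam1 (−4.54), Etnk2 (−5.92) and Tnfrsf13c (−2.68). So it was for Sdc1 (−2.44), Polm (−2.65), Id3 (−2.09), Bcl11a (−0.75), Ctnna1 (−2.49), Lgals1 (−1.36), Mx1 (−3.25), Mx2 (−3.99), Fos (−2.42), Btg2 (−1.07), Hk1 (−1.32) and Insr (−0.96).

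The het effect differed between the stages in 703 genes, and in 13 of the 24 genes named above for het against WT. It was higher in pre-B cells for Maged1 (1.05), Il9r (5.6), Sema4g (5.08), Smoc1 (2.87), Prdm1 (2.05) and Cd86 (1.78). It was lower there for Id2 (−1.24), Adamtsl2 (−3.16), Fam101a (−5.4, with few counts in het), Zscan12 (−4.12), Arhgef39 (−4.38), Id3 (−1.87) and Polm (−1.49). List medians of the het difference were 0.323 for mature B, −0.751 for cell cycle, −0.569 for T lineage, 0.492 for plasmacytoid dendritic and −1.14 for NK genes. For homo they were −0.757 for cell cycle, −0.835 for myeloid, 0.482 for plasmacytoid dendritic and −0.877 for NK genes. Without 1 library some of these medians moved by over 1.5 times: in het to 0.155 for mature B, −0.487 for cell cycle and 0.152 for plasmacytoid dendritic genes, and in homo to −0.463 for cell cycle, −0.441 for myeloid and −0.488 for NK genes at the lowest. With an estimated correlation no list kept its call (adjusted p from 0.476 to 0.899). Most NK and plasmacytoid dendritic genes were lower in pre-B cells, so their medians can restate the pre-pro B effect with its sign turned.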

How the results depend on the processing

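The sex term, XX libraries only, library size as a covariate, the minimum fold, the mouse block, the omission of the 2 shallowest pre-B libraries, the gene span and the expression strata were alternatives chosen only after the results were seen. Simulated changes of 1.5 fold were recovered in 18.3% in pre-B cells (11267 genes) against 57.6% in pre-pro B cells (12091 genes). Pre-B libraries had the larger biological variation (16.3% against 8.13%) and the shallowest library, and which of these lowers the share was not tested. Genotype is confounded with sex, and in pre-pro B cells with depth. In pre-B cells the levelling of abundant counts was seen in the 2 shallowest libraries, homo replicate 3 and, less, het replicate 2. In homo replicate 3 B2m stood at 631 CPM against 214 and 202 in homo replicates 1 and 2, and Eef1a1 at 299 against 113 and 111. In het replicate 2 B2m stood at 314 CPM against 204 and 183 in het replicates 1 and 3, and Eef1a1 at 150 against 106 and 109. Of the named genes none reversed under any alternative. In pre-pro B homo against WT, 12 of 34 stayed called with library size as a covariate and 25 with a sex term. With all 18 libraries 32 stayed called and with no count filter 33. In het, of 8, the numbers were 5, 2, 6 and 7, and 3 in XX libraries. In pre-B cells at least 43 of 44 (homo) and 16 of 16 (het) stayed called under each of these, and of 11 named for homo against het 7 with only the 6 libraries compared and 8 with the replicate block. Over all genes eligible to be named, 9293 called results kept their call over the alternatives and 856 lost it, while of the uncalled ones 5558 stayed uncalled, 526 gained a call and 66 changed sign. For lists the numbers were 986 and 160, and 2096, 62 and 207. Where a value moved, the cause was not tested unless stated.

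Counts below are in the order given. DESeq2 called 466 genes for het and 45 for homo against het in pre-pro B cells and 460 for homo against het in pre-B cells, with a het and homo overlap of 455 in pre-pro B cells. With no count filter, het gave 251, homo against het 43 and the overlap 242 in pre-pro B cells. With all 18 libraries the counts in pre-pro B cells were 1146 for homo, 187 for het, 10 for homo against het and 183 for the overlap, and in pre-B cells 2940, 1584, 662 and 1301. With only the 6 libraries compared, het and the overlap gave 12 each in pre-pro B cells, and in pre-B cells het gave 1141 and homo against het 35. In XX libraries pre-pro B cells gave 903 for homo (604 higher, 299 lower), 3 for het, 86 for homo against het and 3 for the overlap, and pre-B cells 1689 for het, 551 for homo against het and 1187 for the overlap. With a sex term pre-pro B cells gave 605, 7, 0 (1095 at an unadjusted p under 0.05 in edgeR, 45 by DESeq2 without the term) and 7, and pre-B homo against het 359. With library size as a covariate pre-pro B cells gave 213, 40, 0 (1305 at an unadjusted p under 0.05 in edgeR) and 29, pre-B cells 3456, 3005, 1604 and 1929, and the het interaction 1055. Without the 2 shallowest pre-B libraries, pre-B cells gave 3456, 1716, 714 and 1469, and the interactions 1172 for het and 2873 for homo. With a log2 fold of at least 1, which removes genes by construction, the counts were 510 and 15 in pre-pro B cells (homo, het), 920 and 454 in pre-B cells, 4221, 4300 and 4316 for the stage in WT, het and homo, and 466 and 990 for the het and homo interactions. DESeq2 size factors and the stricter count filter moved none of these counts by more than 1.5 times.

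The labels state no link between samples of the same replicate number, but the sexes match across the stages for every number, so the same mice may have given both stages. The stage and interaction fits take the libraries as independent. Over 9 pairs of the same genotype and number across stages, correlations of deviations ran from −0.0664 to 0.315. Within a stage they ran from −0.872 to 0.397 over 18 pairs of the same number. The correlation was 0.859 for pre-B het replicate 2 and homo replicate 3, of unlike number. Among the 3 libraries of their genotype in the other stage, 9 of 18 libraries correlated best with their own number. With the replicate number as a block, the counts were 119 for het, 20 for homo against het and 117 for the overlap in pre-pro B cells, and 1125, 383, 71 and 343 for homo, het, homo against het and the overlap in pre-B cells; other counts stayed within 1.5 times. With each number of a genotype taken as 1 mouse, the block gave 395 for the het interaction (703 without it) and 1355 for homo (1809 without it).

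Leaving out 1 replicate at a time, the counts in pre-pro B cells ran from 1112 to 2059 for homo, 0 to 1901 for het, 0 to 223 for homo against het and 0 to 1690 for the overlap. In pre-B cells they ran from 1055 to 2097, 336 to 756, 52 to 374 and 303 to 1048. Stage counts ran from 7417 to 7551 in WT, 7954 to 8704 in het and 8013 to 8505 in homo, and interactions from 469 to 879 for het and 1349 to 2155 for homo.

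Of the 24 list calls between genotypes, 0 held with an estimated correlation and 6 with fry, which called 9 lists in all. For the stage signature in pre-pro B cells, the median of the pre-B set was 0.25 but p was 0.417 with an estimated correlation and 0.427 with fry, that of the other set −0.13 with 0.243 and 0.236, and with a sex term the pre-B set (0.224) was not called. Left out in turn, replicates moved the medians from 0.108 to 0.385 and from −0.19 to −0.0733 in pre-pro B cells, and from −0.278 to −0.199 and 0.695 to 1.06 in pre-B cells. With 50 genes the pre-B set in pre-pro B cells was the only reversed result (median 0.191, but the direction of camera was down, and it was not called), and the pre-B cell test of the other set gave no value.

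Stricter peaks (fold and −log10 q of at least 5) left 2031 WT and 3862 homo Ikaros peaks in pre-B cells, 1450 and 2536 in thymocytes, and 19 and 5 (pre-B) and 4 and 72 (thymocyte) Aiolos peaks, by construction fewer. Overlaps were then 93.7% of WT and 49.1% of homo Ikaros peaks in pre-B cells, 73% and 41.7% in thymocytes, and 0% of each Aiolos list. Asking for 50% of the peak gave 36.2% of pre-B homo Ikaros peaks, 75.6% of WT and 27.4% of homo thymocyte Ikaros peaks and 16% of WT thymocyte Aiolos peaks. The odds ratio of genes that rose near homo peaks was 0.963 at 2 kb, 1.27 (called) at 50 kb, 1.4 (called) with stricter peaks and 1.62 (called) over the gene span. Near homo-only peaks it was 0.729 (called, lower) at 2 kb, 1.14 at 50 kb and 1.47 over the span. For genes that fell near homo-only peaks it was 1.22 and no longer called with stricter peaks. Motif alternatives were not run, as no genome was at hand.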

Other observations

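The counts of other splits of the samples in this part were chosen only after the results were seen.

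Other splits of the 6 libraries of a comparison into 3 against 3 are 10 in number with the real one, too few for a share under 0.05. In pre-pro B cells the real split called 2730 genes for homo and 68 for het and the highest other split 0 for each, while homo against het called 2 and the highest other split 6. In pre-B cells the real split called 1811 for homo and 705 for het and the highest other 0 for each. For homo against het the real split called 216 and another 1854: that one parts het replicate 2 and homo replicate 3, the shallowest libraries, from most others and points to a structure of the samples. For the stage the real splits called 7997 (WT), 8477 (het) and 8594 (homo), and the highest other 0 for each. Of 40 splits for each interaction, 1 was as large as the real value, the real one itself (703 for het, highest other 682, and 1809 for homo, highest other 1161). The other splits that called the most kept the pre-B genotype groups whole (4 for het, 444 to 682 genes, and 2 for homo, 1083 and 1161). Among the 33 for each genotype that kept neither stage whole the highest edgeR count was 0. Splits that kept the pre-pro B groups whole called 0 genes for het (2 splits) and 0 to 157 for homo (4 splits). The count thus mostly follows the pre-B genotype effect, and these splits do not set the interaction apart from it.

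Lists called in pre-pro B cells numbered 5 for homo (highest other split 6), 7 for het (8) and 5 for homo against het (11). In pre-B cells they numbered 2 for homo (3), 1 for het (5) and 4 for homo against het (4). Splits that called at least as many lists as the real one numbered 5, 3 and 6 of 10 in pre-pro B cells and 6, 9 and 2 of 10 in pre-B cells.

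Peaks inside gene spans made up 45.1% and 46.9% of the WT and homo Ikaros peaks in pre-B cells, and 53.7% and 67.7% in thymocytes.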
